A study of Homo sapiens with 6 samples.

How the data were processed

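The series held 6 AGS samples, 3 labelled as anti-RBM8A immunoprecipitates and 3 as input, with replicate numbers 1 to 3 in each group and the same batch label throughout. Per the labels' protocols, cells were lysed, the lysate was pre-cleared and incubated with antibody, RNA on the beads was extracted and treated with DNase, and no crosslinking step is described. The 3 immunoprecipitates each had 1 deposited peak list, and data of the inputs were not analysed here, so immunoprecipitate and input were not compared directly.

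Per the submitters' processing notes, FastQC, HISAT2, SAMtools, GATK and MACS2 were used, and their versions, roles and settings are not given in the sources used here. Each list has the narrowPeak layout and was called on 1 replicate, not on a pool. The deposited lists give each peak a fold enrichment, which is a ratio of the pileup to the expected level, by the authors. Which sample gave the expected level, the replicate's own input or another background, is not given in the sources used here. They also give a −log10 p-value and a −log10 q-value, computed by the authors' caller. The deposited score column is 10 times the −log10 q-value with the decimals dropped, so it was not used separately. The lowest −log10 q-values were 1.32, 1.36 and 1.32 in replicates 1, 2 and 3, above the 1.30 that belongs to a q of 0.05. The notes name hg38, but the sequence names in the lists (such as chrUn_gl000220 and chr17_ctg5_hap1) are those of hg19, and 0 peaks lie past the end of an hg19 chromosome. On the sequence names, the coordinates were taken as hg19 and were not converted. The count of 0 peaks past an end was not compared with another build, so it does not decide between builds. The gene table used here is of another build, so its coordinates were not used, and no peak was assigned to a gene, exon or intron.

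The deposited lists hold no read totals, so the sequencing depth of the libraries is unknown. The depth at the summit of each peak was recovered instead, in a step chosen after the data were seen. MACS2 computes the fold as pileup over expected level, after adding 1 to each, and the p-value from a Poisson distribution with that expected level. Whole pileups up to 400 were searched for the one that gave both the deposited fold and the deposited −log10 p-value within 0.0005. A whole pileup was found for 1476 of 1480, 2150 of 2155 and 1800 of 1802 peaks, or 99.8% ± 0.083 (SD, n = 3). With the −log10 p-value altered, 2 of 500 peaks (0.4%) still gave one. The remaining 4, 5 and 2 peaks, on chrUn_gl000220, were too deep and were given an estimated pileup. The lowest expected level in a list was 0.422, 0.400 and 0.374. Summits within 0.5% of it, 50.5%, 42.6% and 40.1% of each list, are called at the floor. Exact 95% Poisson intervals of the pileup cover counting error only, and do not allow for the choice of the summit.

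Peaks of all 3 lists were joined into union regions wherever they overlapped. A peak counted as shared when at least 1 bp overlapped. The observed share of each list in each other list was set against 1000 placements of the second list on chromosomes 1 to 22, X and Y, with a one-sided permutation p and Benjamini-Hochberg adjustment over 6 ordered pairs. Placement within the exons of the own gene had been planned and was replaced by uniform placement on the own chromosome, and a shift by 0.1 to 1 Mb was added after the data were seen. Within each list, medians of shared and unshared peaks were compared by 100000 two-sided permutations, adjusted over 3 replicates. Chromosome lengths were those of hg19 as held by pyranges. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pyranges 0.1.4 and matplotlib 3.10.9.

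The rule for what is named was set before the data were examined. It took 15 genes, or, without annotation, the 15 positions shared by all 3 replicates with the highest mean percentile rank of the best peak by fold. Of 9 planned comparisons, 6 need gene annotation of the files' build and were not run: target genes of all 3 replicates, location of summits, share in last exons, distance to exon ends, single-exon genes, and gene lists. The counts of shared regions, the density by chromosome and the recurrence by pileup were added after the data were seen. Chromosome Y was left out of the account by chromosome. Alternatives were a stricter q or fold, larger overlaps, summits within 100 bp, peaks under 10 kb, the shift, and leaving out each replicate.

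The statistics were tested on simulated data. Pileups were recovered for 100% of 400 simulated peaks. These were made with the formulas that the recovery inverts, so the result checks the search and not the caller's formulas. With 0%, 5%, 20% and 40% of planted overlap between lists of the size of replicates 1 and 2, the mean excess over random placement was -0.0577, 4.86, 19.7 and 39.4 percentage points over 5 runs each. Planted peaks were exact copies, and the rest of the second list was placed uniformly. The clusters of the real second list were therefore not simulated. The permutation test of medians gave p of at most 0.05 in 5% of 1000 runs without a difference, and that of shares in 5.7%. Planted differences, a fold 10% higher or a share of 50% against 30%, were found in 100% of runs.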

Results

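RNA recovered with an anti-RBM8A antibody was profiled by RNA immunoprecipitation and sequencing (RIP-seq) in AGS, a human gastric adenocarcinoma cell line grown without treatment. RBM8A, also called Y14, is a core protein of the exon junction complex, which is deposited on spliced RNA near exon boundaries. The 6 samples were 3 immunoprecipitates with this antibody and 3 input samples. None was an immunoprecipitate with a control antibody, so RNA bound by RBM8A cannot be told apart from RNA held nonspecifically. Peaks called by the authors separately in each immunoprecipitate were analysed, and data of the input samples were not analysed here. The labels do not say whether the replicates were separate cultures, so the spread between them may be technical. All positions are hg19 coordinates, counted from 1, and peaks carry no strand.

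The first comparison asked where in the genome RNA recovered with the antibody was found and how strongly it was enriched. The lists held 1480 peaks in replicate 1, 2155 in replicate 2 and 1802 in replicate 3, a mean of 1812 ± 338 (SD, n = 3). Chromosome 19 was the most densely covered chromosome in every replicate, with 3.16 ± 0.627 peaks per Mb (SD, n = 3) and 10.3% ± 0.716 of all peaks (SD, n = 3). It was followed by chromosome 20 with 1.55 ± 0.429, chromosome 17 with 1.27 ± 0.254 and chromosome 1 with 0.956 ± 0.181 peaks per Mb. The sparsest were chromosome 18 with 0.115 ± 0.0462, chromosome 4 with 0.225 ± 0.0742 and chromosome X with 0.230 ± 0.0870 peaks per Mb. Chromosome 18 held 8, 6 and 13 peaks in replicates 1, 2 and 3, against 160, 229 and 171 on chromosome 19, and the ranges of these chromosomes did not overlap. These chromosomes were picked as the extremes of the ranking, and their counts come from the same 3 lists. The counts are thus paired within replicates, and the difference was not tested. Among peaks with a −log10 q of at least 5, the share on chromosome 19 was 17.0%. Densities per Mb were not adjusted for the genes of a chromosome or their expression in AGS cells. The ranking of chromosomes therefore need not reflect RBM8A binding. The mitochondrial genome held 0 peaks in each list. Whether mitochondrial reads were kept before peak calling is not given in the sources used here.

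**Figure D1:**
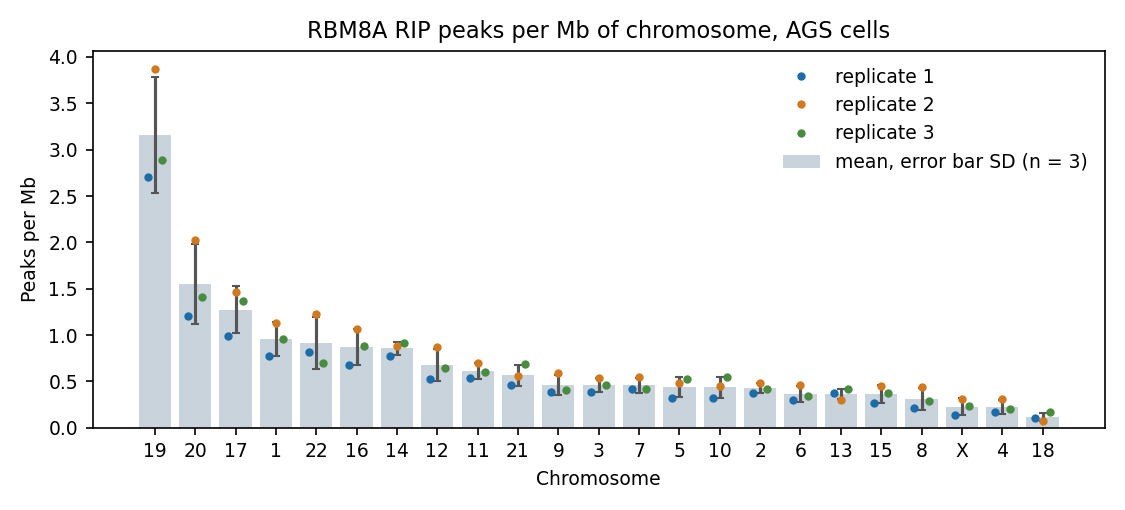
Peaks per Mb of each hg19 chromosome (y axis) for the chromosomes named on the x axis, with 1 point per replicate, bars for the mean and error bars for the SD (n = 3). Chromosome 19 stands highest at 3.16 peaks per Mb and chromosome 18 lowest at 0.115.

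Fold enrichment, a value the authors' peak caller gave to each peak, was used to rank, filter and test peaks only within a list. The sources used here do not say which background sample it is measured against. Its median was 4.15, 4.16 and 3.97 in replicates 1, 2 and 3, and its highest value was 54.2, 78.6 and 70.6. A fold of at least 10 was reached by 10, 23 and 17 peaks, and a fold of at least 5 by 240, 575 and 377. The median −log10 q was 2.40, 2.64 and 2.66, and 15.3% ± 1.79 of peaks (SD, n = 3) reached a value of 5, or 198, 336 and 305 peaks. Median peak widths were 1870, 1557 and 1810 bp. Peaks of at least 10 kb made up 9.46% ± 1.59 of each list (SD, n = 3) and held 69.4%, 62.2% and 63.2% of the 10.0, 11.5 and 10.5 Mb covered.

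Few fragments piled up at the summit of most peaks, and the fragments of a whole peak were not counted. The pileup at the summit, recovered from the authors' fold and p-value, had a median of 6 fragments in each replicate. It was 4 or 5 in 42.3%, 39.2% and 42.8% of peaks, and at least 10 in 23.9%, 25.5% and 24.4%. An exact 95% Poisson interval runs from 1.09 to 10.2 for a pileup of 4 and from 4.80 to 18.4 for a pileup of 10. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules. They also do not allow for the choice of the summit within a peak that had passed the q cutoff.

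The second comparison asked how far the replicates shared positions. Union of the 3 lists gave 3584 regions, of which 433 (12.1%) were found in all 3 replicates, 656 (18.3%) in 2 and 2495 (69.6%) in 1. Such a region can join peaks of 2 lists through a peak of the other, and 416 of the 433 had at least 1 bp covered in all 3 lists. Regions of all 3 replicates were most numerous on chromosomes 1 with 63, 19 with 52, 2 with 26, 14 with 24 and 20 with 23. On chromosomes 1 to 22, X and Y, 428 regions lay in all 3 replicates, against a mean of 1.13 and a maximum of 5 when peaks were placed at random on their own chromosome (one-sided permutation p = 0.001). Moving peaks by 0.1 to 1 Mb, which roughly keeps the density of the surrounding megabase, gave a mean of 6.56 and a maximum of 17 (one-sided permutation p = 0.001). In either placement each peak moved by itself, which broke up close clusters. Both p-values are the smallest that 1000 placements can give. Regions in all 3 replicates numbered 46 when only peaks with a −log10 q of at least 5 were used in each list. Without replicate 1, 2 or 3, regions of both remaining replicates numbered 713, 601 and 671.

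Between pairs of lists, the share of peaks overlapped by at least 1 bp ranged from 33.8%, for replicate 2 in replicate 1, to 49.6%, for replicate 1 in replicate 2, with a mean of 40.7% over the 6 ordered pairs. The mean share with summits within 100 bp of each other was 11.4%. Random placement on the own chromosome gave a mean of 0.897% and a maximum of 2.05%. Each of the 6 pairs exceeded all 1000 placements, with an adjusted one-sided permutation p of 0.001. These placements do not hold expression constant, so the excess includes the effect of which transcripts AGS cells contain.

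The 15 regions named here were those of all 3 replicates with the highest mean percentile rank of their best peak by fold. No annotation of the files' build was used, so they are given by position and not by gene. The mean and SD of fold describe each list's own best peak in the region, and differences in fold between replicates were not tested. All 15 had a base covered in all 3 lists, and in 13 the best peaks of the 3 lists shared a base. In the region of chromosome X, the best peak of replicate 1 met those of replicates 2 and 3 only near an end. In that of chromosome 2 from 54856677, the best peak of replicate 3 met those of replicates 1 and 2 only near an end. The values of these regions are therefore partly of different peaks. The strongest was a region of chromosome 1 from 16840829 to 16979918, where the best peak had a fold of 67.8 ± 12.5 (SD, n = 3). That best peak was 138771, 139090 and 138777 bp wide in replicates 1, 2 and 3, with the expected level at the floor in each. Its summit pileups were 76, 109 and 96 fragments, with 95% Poisson intervals of 59.9 to 95.1, 89.5 to 131 and 77.8 to 117. Next came a region of chromosome 16 from 21413559 to 21876058 with a fold of 20.8 ± 6.87 and pileups of 30, 44 and 40. A second region of chromosome 1, from 1571174 to 1654338, had a fold of 12.9 ± 3.35. Chromosome 2 held a pair of nearby regions, from 54856677 to 54859901 with a fold of 8.96 ± 1.71 and from 54876188 to 54890497 with a fold of 10.2 ± 0.791. In the latter, the best peak ran from 54885108 to 54890278 in replicate 1 and from 54885101 to 54890450 in replicate 3, but from 54876188 to 54881145 in replicate 2, so its values are of different peaks. Summit pileups of the best peaks lay between 10 and 14 fragments in both regions. Chromosome 20 held 3 of the 15 regions, from 32693403 to 32699911 with a fold of 8.40 ± 2.73, from 42302452 to 42345029 with 10.4 ± 3.20, and from 57242596 to 57244538 with 8.57 ± 1.99. In the region that starts at 42302452, the best peaks of replicates 1 and 3 did not overlap.

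Chromosome 7 held a region from 72413109 to 72670964 with a fold of 8.06 ± 2.03 and another from 102115052 to 102286262 with 10.7 ± 3.85. On chromosome 1, the region from 21071408 to 21076298 had a fold of 8.35 ± 1.67, with pileups of 19, 19 and 18. A region of chromosome 17 from 44395522 to 44671239 had a fold of 8.83 ± 2.55. The region of chromosome 8 from 145206170 to 145476759 had a fold of 7.87 ± 1.48, and that of chromosome X from 3747313 to 3834096 had 8.36 ± 1.86. A region of the unplaced scaffold chrUn_gl000220 from 87227 to 104138 ranked 5 of the 15, with a mean fold of 19.6 ± 15.9. Its folds were 12.8, 8.11 and 37.7 in replicates 1, 2 and 3. In 8 of the 15 regions the best peak was at least 10 kb wide in every replicate, compared with 39 of all 433 shared regions. In 7 of the 15 it was at least 50 kb wide in every replicate. What gives rise to such wide peaks was not settled, so a high fold there need not mark strong binding. The expected level at the summit lay within 0.5% of the lowest level in its list in all 3 replicates for 6 of the 15.

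**Figure D2:**
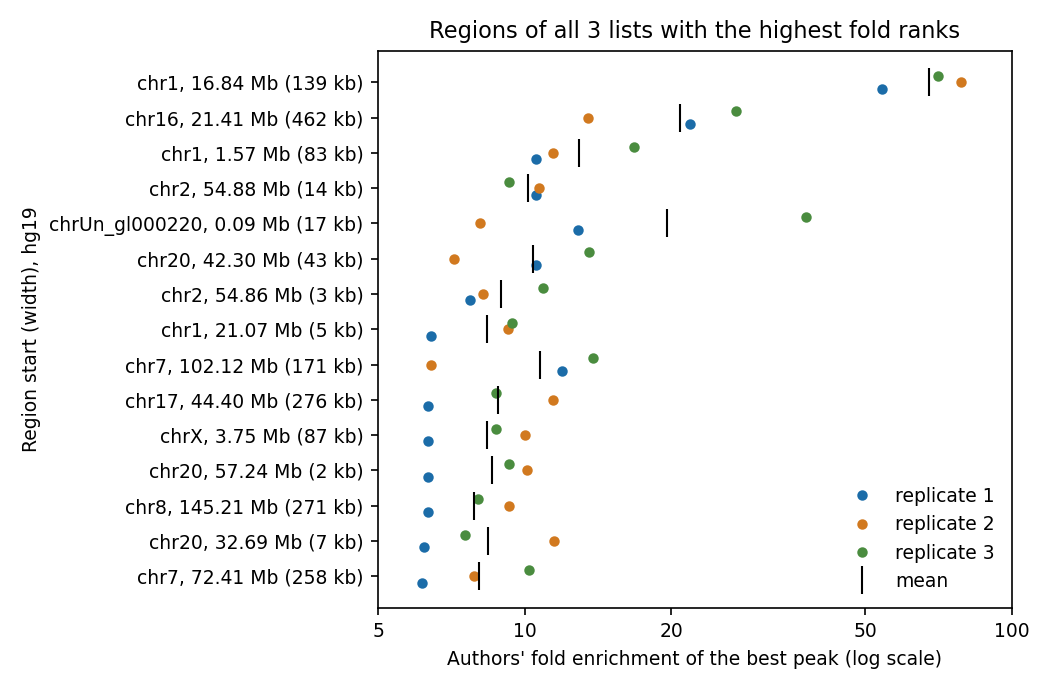
Authors' fold enrichment of the best peak (x axis, log scale) in the 15 named regions (y axis, by hg19 start and width), with 1 point per replicate and a line at the mean (n = 3). The top region of chromosome 1 has folds of 54.2, 78.6 and 70.6 in replicates 1, 2 and 3, and the scaffold region has folds of 12.8, 8.11 and 37.7.

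The third comparison asked whether peaks shared by all replicates differed in enrichment from those of a single replicate. Within each list, peaks overlapped in both other replicates were set against peaks overlapped in neither. Shared peaks numbered 479, 478 and 477 in replicates 1, 2 and 3, and unshared peaks 570, 1095 and 830. The median fold was higher in shared peaks by 0.383 in replicate 2 (4.29 against 3.90, adjusted permutation p = 0.0126). It was 4.22 against 4.10 in replicate 1 (adjusted permutation p = 0.5) and 3.97 against 3.95 in replicate 3 (adjusted permutation p = 0.27), so that 1 of 3 replicates passed the two-sided test. The call in replicate 2 was lost with an overlap of at least 50% of both peaks (0.228), with a −log10 q of at least 5 (0.227) and among peaks under 10 kb (0.365). Replicate 3 passed when only 1 other list was used, with differences of 0.0452 without replicate 1 and 0.0691 without replicate 2. In replicates 1 and 3 the difference was below 0, at -0.063 and -0.156, with a −log10 q of at least 5, and in replicate 1 it was -0.0671 among peaks under 10 kb. The caller's q cutoff lets deep summits pass at a lower fold than shallow ones. In replicate 2, a summit of 4 fragments was listed with a fold of 3.57 and one of 17 with 2.43. Unshared peaks had lower pileups, so the medians compare groups held to different minimum folds and say little about enrichment.

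Summit pileup separated the same groups in every replicate, a comparison chosen after the data were seen. Its median was 9 fragments in shared against 5 in unshared peaks in replicate 1, 11 against 5 in replicate 2, and 10 against 5 in replicate 3. The adjusted two-sided permutation p was 1e-05 in each, the smallest that 100000 permutations can give. Median widths of shared peaks were 2550, 2932 and 2771 bp, and those of unshared peaks were 1570.5, 1180 and 1493.5 bp. Of peaks with a pileup of 4 or 5, 10.97% ± 3.50 were overlapped in both other replicates, rising to 18.3% ± 4.07 at 6 or 7, 31.9% ± 11.1 at 8 or 9 and 59.4% ± 8.08 at 10 or more (SD, n = 3). The difference between the highest and lowest of these classes was 51.5, 42.5 and 51.3 percentage points in replicates 1, 2 and 3, each with an adjusted two-sided permutation p of 1e-05. The mean difference was 48.4 points, and 12.99 points with summits within 100 bp. Peaks of a list lie in clusters, and these permutations treat them as independent. A peak counts as shared only where the other lists also pass the caller's q cutoff, and the lowest pileup listed was 4. Where coverage is alike between replicates, deep summits therefore recur more often than shallow ones through the cutoff itself. Pileup was also not adjusted for expression, so its difference is not a measure of enrichment.

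**Figure D3:**
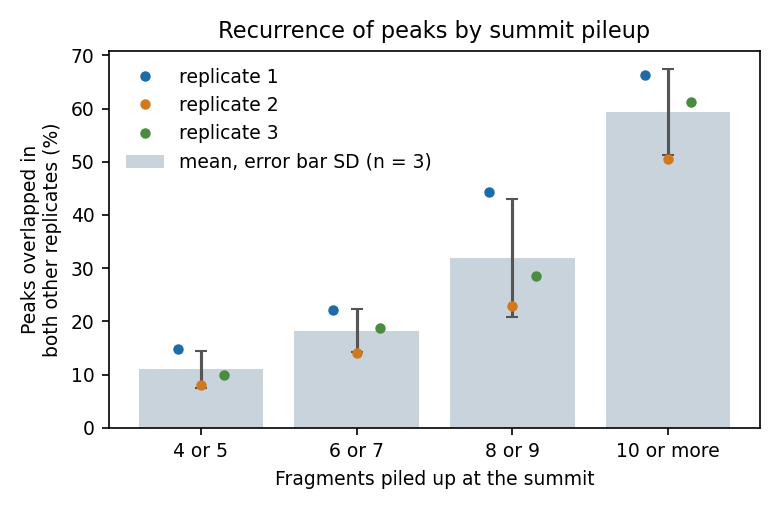
Percentage of peaks overlapped in both other replicates (y axis) by the number of fragments at the summit (x axis), with 1 point per replicate, bars for the mean and error bars for the SD (n = 3). The mean rises from 10.97% at 4 or 5 fragments to 59.4% at 10 or more.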

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

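Among the tests and settings below, the shift, the restriction to peaks under 10 kb, the leave-one-out runs, the base common to all lists and all results on shared regions, chromosomes and recurrence by pileup were chosen only after the data were seen. The overlap between lists stayed above every random placement under all settings run, with a mean share of 28.8% when at least 50% of both peaks had to overlap (200 placements), 11.4% for summits within 100 bp, 32.0% with a −log10 q of at least 5, 37.1% among peaks under 10 kb and 39.98% to 41.7% without 1 replicate. Recurrence in both other lists rose with pileup by 48.4 percentage points, by 34.4 with at least 50% overlap, 12.99 for summits within 100 bp and 46.1 among peaks under 10 kb. Without 1 replicate, recurrence in the 1 other list left rose by 46.3 to 49.1 points. With a −log10 q of at least 5, peaks numbered 198, 336 and 305 in replicates 1, 2 and 3, regions of all 3 replicates 46, and the share on chromosome 19 was 17.0%. That share was 11.1% among peaks under 10 kb and 10.1% to 10.7% without 1 replicate. With a fold of at least 5, peaks numbered 240, 575 and 377. These filters keep fewer peaks by construction. Regions with a base common to all 3 lists numbered 416. Regions of both remaining replicates numbered 601 to 713 when 1 was left out, since fewer lists then have to share them, and mean peak counts were 1641 to 1979. The fold difference between shared and unshared peaks depended on the setting, and the cause was not tested. In replicate 2 it was 0.228 with at least 50% overlap, 0.227 with a −log10 q of at least 5 and 0.365 among peaks under 10 kb, with adjusted permutation p-values of 0.35, 0.11 and 0.065, and 0.269 to 0.283 without 1 replicate, which passed. It turned negative in replicate 1 with a −log10 q of at least 5 (-0.063) and among peaks under 10 kb (-0.0671), and in replicate 3 with a −log10 q of at least 5 (-0.156), with adjusted permutation p-values of 0.11, 0.71 and 0.11. Without 1 replicate it was 0.0498 to 0.116 in replicate 1, and 0.0452 to 0.0691 in replicate 3, where both values passed (permutation p = 0.0012 and 0.0041). Not run were the 27 alternatives of the 6 comparisons that need annotation, and placement within gene bodies. No paired analysis was possible because only the immunoprecipitates had peak lists, so the inputs that share their replicate numbers could not enter a fit. Summit pileups of 4 to 6 fragments limit what single peaks can show.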

Other observations

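All tests and patterns in this part were chosen only after the data were seen. No biological explanation was tested for the 3 patterns weighed, since no other group with peaks and no annotation of the files' build was used.

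Some parts of the genome held many peaks in every replicate. Of the 1013 windows of 1 Mb that held a peak in any list, 11 held at least 8 peaks in every replicate. The fullest lay on chromosome 1 from 1 to 2 Mb, with 16, 17 and 9 peaks in replicates 1, 2 and 3, and on chromosome 14 from 105 to 106 Mb, with 14, 14 and 13. Chromosome 19 held 3 of them, from 10 to 11 Mb with 10, 11 and 10 peaks, from 39 to 40 Mb with 11, 12 and 9, and from 41 to 42 Mb with 8, 10 and 9. The window of chromosome 2 from 54 to 55 Mb, with 9, 8 and 10 peaks, contained both of that chromosome's strongest shared regions. Others lay on chromosome 1 from 154 to 155 Mb and from 156 to 157 Mb, chromosome 9 from 131 to 132 Mb, chromosome 22 from 36 to 37 Mb and chromosome 3 from 47 to 48 Mb.

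The scaffold chrUn_gl000220, known to carry ribosomal RNA gene repeats, held 11, 15 and 3 peaks in replicates 1, 2 and 3. Its longest low-fold peak began at 113381, 113365 and 113408 and had folds of 1.86, 1.33 and 1.20, at estimated pileups of 65199, 66965 and 66977 against expected levels of 35081, 50348 and 56000.

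Clusters also held at short range. Another summit of the same list lay within 20 kb for 46.3%, 55.3% and 51.5% of peaks in replicates 1, 2 and 3. Moving each peak by 0.1 to 1 Mb gave means of 8.25%, 11.04% and 9.11% (one-sided permutation p = 0.001, the smallest that 1000 placements can give). The smallest gap between an observed share and the highest of its placements was 34.4 percentage points, which argues against the density of the surrounding megabase as the whole cause. Several peaks on the exons of 1 transcript, or 1 broad enrichment divided by the caller, may each give such neighbours, and without annotation these were not tested.

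A second pattern was the partial overlap of the lists. Peaks drawn only to the same wide neighbourhoods would overlap as often after a shift of 0.1 to 1 Mb, but the observed share exceeded the highest shifted placement by at least 31.3 percentage points in all 6 pairs. Such shifts do not keep a peak on its own transcript. They therefore cannot tell shared binding positions from mere sharing of the same expressed transcripts. Counting noise as the cause of the peaks not shared was weighed only among strong peaks. For weaker peaks it was not weighed. Of peaks with a −log10 q of at least 10, 81.3% on average were overlapped in both other lists, against 84.6% when each summit was redrawn from a Poisson distribution at the lower 95% bound of its pileup. The observed shares were 84.2%, 81.7% and 78.0% of 38, 71 and 50 such peaks, against means of 78.3%, 87.4% and 88.1% in the draws. Replicate 3 alone fell below the 2.5th percentile of its draws (65.8%, 78.9% and 80%). Use of the lower bound favours noise as the cause. Noise alone and a further difference between replicates cannot be told apart at these numbers.

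The last pattern was the width of many peaks. The expected level lay within 0.5% of the lowest in its list for 65.3% ± 2.52 of summits in peaks of at least 10 kb and for 39.1% ± 5.70 in peaks under 1 kb (SD, n = 3), a mean difference of 26.1 percentage points with a permutation p of 1e-05 in each list. Fragments that bridge a gap, counted across it in the immunoprecipitate and not in the background, may give such peaks, but long unspliced RNA and reads shared by near-identical copies also stay open and were not tested. Chaining of neighbouring low peaks by chance was weighed through the ends of overlapping wide peaks, whose median difference was 1.54%, 3.35% and 10.7% of the width in the 3 pairs of lists. The last value passed the bound of 10%, though in regions of all 3 replicates the medians were 1.47%, 1.49% and 1.81%, and 45.0% of wide peaks had no wide peak of another list to compare, so chance chaining was not excluded.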
